A study of Mus musculus with 4 samples.

How the data were processed

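RNA was measured by sequencing in 4 libraries from mouse medulloblastoma cells of the Sonic Hedgehog subtype, grown as neurospheres and named SmoWT in the labels. The cells came from spontaneous tumours of Ptch1+/-, Trp53-/- mice. Per the labels' protocols, 2 libraries were made from cells given the solvent DMSO and 2 from cells given 0.1 µM GDC0449 (vismodegib, an inhibitor of the Hedgehog receptor component Smoothened), both for 24 h. Total RNA was taken with TRIzol. The labels do not say how RNA was selected, whether the library kit marked strand, or whether the 2 replicates of a group were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

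Per the submitters' processing notes, adapters were trimmed with Trim Galore, reads were mapped to the mouse build mm10 with HISAT2, and reads per gene were counted with HTSeq 0.11.1. The same notes name DESeq2 1.26.0 for the authors' own test, with thresholds of 1.5-fold and a false discovery rate of 0.05. The annotation release, the strand setting of the counting and the options of the aligner are not given in the sources used here. The deposited table holds raw counts per gene for each library and, beside them, FPKM values that the authors computed from reads per gene, gene length and depth. Both kinds of value were read as deposited. The tool behind the FPKM values is not given, and 546 genes have 0 counts in all 4 libraries with an FPKM of at least 1 in all 4. Counts and FPKM were therefore not made from one assignment of reads to genes.

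The table has 55573 genes. Another 6 entries name no gene and were left out of library sizes and tests: 5 classes of unassigned reads from HTSeq and 1 stray header. Of all reads in the table, those in no gene made up 12.3% and 13.2% in the DMSO libraries and 14.3% and 14.4% in the GDC0449 libraries. Ambiguous reads made up 4.73% to 4.91% and reads with more than 1 alignment 10.4% to 10.7%; the remaining classes held 0. Reads in genes numbered 20113419 and 16329721 in DMSO replicates 1 and 2, and 20790030 and 20711391 in GDC0449 replicates 1 and 2. Gene symbols, biotypes and coordinates (GRCm38, the assembly called mm10) were taken from GENCODE M21, which held 55480 of the 55573 identifiers. Where identifiers shared a symbol, the one with the most reads kept it. Without a stated strand setting, counts of overlapping and antisense genes are uncertain. The same holds for families with near-identical copies, such as histone and ribosomal protein genes, because reads with more than 1 alignment were not counted.

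Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default expression filter, and the quasi-likelihood test with group as the only term, on all 4 libraries. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a fold change over 1.5 in either direction. Standard errors are the log2 fold change divided by the square root of its F statistic. Levels are CPM, the counts scaled to a common library total with TMM factors, computed here from the counts and given as mean ± SD with n = 2. The estimated biological coefficient of variation was 4.82%, and the prior degrees of freedom were 49.9, so the spread of each gene was taken largely from genes of similar level. Detection floors cover counting error only, and bootstrap intervals cover the spread between genes. A count of 0 was read against a floor of 3 counts.

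Before the data were examined, 39 gene lists, the design, the alternatives and the rule for naming genes were fixed. The lists cover Hedgehog targets and signalling, cilia, the cell cycle, granule neuron stages, other cerebellar and non-neural cell types, metabolism, ribosomes, stress and other signalling pathways. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 35 lists tested. Calls of single members were counted over all genes and also adjusted over the list alone. Named genes are a panel of Hedgehog and tumour genes whatever their values, the 12 highest and 12 lowest fold changes, and members of each list. The highest and lowest were taken among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted or clone-named models, pseudogenes and haemoglobin, mitochondrial and ribosomal RNA genes. Of each list, up to 4 called members with the smallest p were taken, or up to 2 members where none was called. This named 133 genes, of which some are not reported here. Other list members given in the text are marked by their calls and were chosen after their values were seen.

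Alternatives were relative log expression and upper-quartile scaling, no filter, a filter at 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, robust dispersions, a replicate block, leaving out each library in turn, counts thinned to the smallest library, other thresholds, an estimated correlation between genes, and fry. Where a library was left out, the lone sample of its group was assumed to vary like the other group. Added after seeing the data were limma on log2(FPKM + 1) over genes with an FPKM of at least 1 in 2 libraries, and the legacy form of the quasi-likelihood fit. Alternatives meant for a table with FPKM alone were not run, because the table holds counts.

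The scripts were tested on simulated data: counts drawn for 15454 tested genes from these libraries' means and sizes, with 200 genes changed. In this simulated comparison of GDC0449 with DMSO, edgeR recovered 59.7% of genes changed 1.6-fold, 83.6% of those changed 2-fold and 93.9% of those changed 4-fold. It called 2 unchanged genes and gave 0 wrong directions. Each tested gene was simulated with the fitted spread for its level and no spread of its own, as the edgeR fit largely assumes. The few false calls therefore do not give the error rate in the real libraries. Camera at the preset correlation called 3 of 3 shifted lists and 1 of 27 unshifted lists. With an estimated correlation it called 0 of 3 and 0 of 27, so that setting missed shifted lists at this number of libraries. Simulated genes were drawn independently of each other, while the estimated correlation in the real fatty acid synthesis list was 0.864. The simulation therefore cannot show how often either setting errs on lists of correlated genes. Directional fry called 3 of 3 and 4 of 27.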

Results

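Transcript levels were compared between SmoWT neurospheres kept for 24 h with 0.1 µM GDC0449 and neurospheres kept with DMSO, with 2 libraries in each group. SmoWT cells are mouse medulloblastoma cells of the Sonic Hedgehog subtype, a cerebellar tumour that resembles granule neuron progenitors. Loss of Ptch1, the inhibitory Hedgehog receptor, activates Smoothened in such tumours. The series title names Smoothened inhibition as the subject, so the comparison asks which transcripts differ after 24 h of the inhibitor. The libraries held 16329721 to 20790030 reads in genes, and between 22309 and 23821 genes had at least 1 read. Replicates differed by more than sampling noise, with a chi-square of 4.25 per gene in DMSO and 3.42 in GDC0449. All were kept as separate samples. The first principal component held 73.9% of the variance and separated the groups.

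Hedgehog targets were lower as a list, with 6 of 10 called lower and 1 higher. Gli1, the transcription factor that reports pathway activity, fell 7.61-fold, from 272 ± 12.9 CPM in DMSO to 35.7 ± 4.28 CPM in GDC0449 (SD, n = 2). Of 25 genes of the integrated stress response and unfolded protein response 19 fell and 1 rose, with Trib3 falling 8.53-fold. Of 25 cholesterol and 11 fatty acid synthesis genes 21 and 7 rose. Lists of early postmitotic and mature granule neuron genes were higher, with 11 of 33 and 11 of 24 members called higher and 1 mature gene lower. The neuronal adhesion gene Cntn2 rose 2.97-fold, from 142 ± 9.19 to 421 ± 26.6 CPM. DNA replication and ribosome biogenesis genes were lower as lists by smaller amounts, with 3 of 55 and 2 of 38 members called. With an estimated correlation between genes, 0 of the 35 lists tested was called with camera, at a smallest adjusted p of 0.136. In that setting 7 lists had an unadjusted p under the threshold. The estimate itself lay below the preset 0.01 for some called lists, such as Hedgehog targets at -0.0733. For others, such as cholesterol synthesis at 0.431, it lay above.

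Of 15472 genes tested with edgeR, 1343 were higher and 596 were lower in GDC0449, together 12.5% of those tested. Over 2-fold, 648 were higher and 312 lower. At adjusted p alone, without a fold threshold, 5587 genes passed, 2794 higher and 2793 lower, so the excess of higher calls over all genes depended on the fold threshold. Below a mean of 5 CPM it did not, with 699 higher and 234 lower, and at 5 CPM or more there were 2095 and 2559. The median log2 fold change of all tested genes was 0.01. With the fold threshold, higher calls made up 69.3% of all calls, and the share was larger among weakly expressed genes: below a mean of 5 CPM 674 genes were higher and 222 lower, and at 5 CPM or more 669 and 374. Protein-coding genes accounted for 1104 of the higher and 487 of the lower calls. Fewer genes were called when either control library was left out. Such a fit takes its spread from the GDC0449 pair alone, so the drop cannot be laid to the control samples themselves. That pair was not the wider one, with a median absolute log2 difference of 0.103 against 0.125 in DMSO. What caused the drop was not tested. Calls of single genes lost in these fits, given below, are part of this drop over all genes. Without DMSO replicate 1 there were 624 higher and 384 lower genes, and without DMSO replicate 2 there were 500 and 351.

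**Figure D1:**
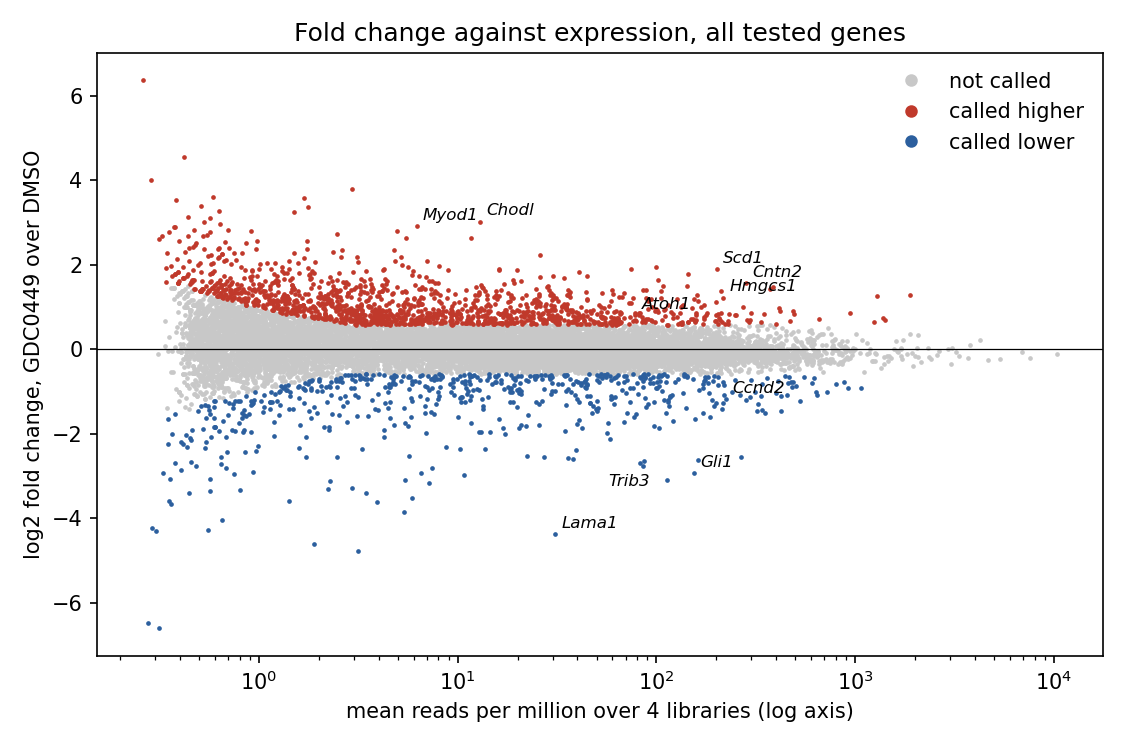
Log2 fold change of GDC0449 over DMSO (vertical axis) against mean CPM over the 4 libraries on a log axis (horizontal axis) for the 15472 tested genes, each point 1 gene, red if called higher, blue if called lower and grey if not called. Below 5 CPM the 674 higher calls outnumber the 222 lower calls, and Lama1, Trib3 and Gli1 are among the lowest of the abundant genes.

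Among the Hedgehog panel, the largest falls were in genes of the Hedgehog target list, but not every panel gene of that list fell. Gli1 (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974) had a log2 fold change of -2.93 with a standard error of 0.07 and an edgeR adjusted p of 1.67e-36. Hhip (ENSMUSG00000064325, chromosome 8, 79965851 to 80058006), a secreted Hedgehog antagonist, fell from 61.6 ± 2.31 to 10.4 ± 0.393 CPM (adjusted p = 1.10e-28). Ptch1 (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598) fell by less, 1.95-fold, from 15.7 ± 0.466 to 8.05 ± 0.543 CPM (adjusted p = 3.44e-08). The counts do not separate its mutated from its intact allele. Ccnd2, which encodes a cyclin of G1 phase, fell from 309 ± 10.9 to 136 ± 1.59 CPM (adjusted p = 1.40e-22).

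Mycn (ENSMUSG00000037169, chromosome 12, 12936093 to 12941914), which encodes an oncogenic transcription factor, was at 1307 ± 36.5 CPM in DMSO and 898 ± 19.5 CPM in GDC0449. Its difference of 1.46-fold passed the adjusted p at 1.63e-11 but lay under the 1.5-fold threshold. On log2(FPKM + 1) it passed, with a log2 fold change of -0.71. Gli2 was at 199 ± 19.5 and 133 ± 6.34 CPM, with a log2 fold change of -0.58 that also missed the fold threshold. It passed with DESeq2, at -0.59, without DMSO replicate 2, at -0.68, and without GDC0449 replicate 1, at -0.63. Ccnd1, Sufu and Smo had log2 fold changes of -0.31, -0.21 and -0.16, and none was called. The drug's target Smo was at 140 ± 6.14 and 125 ± 7.58 CPM (adjusted p = 0.062). Trp53 counts were 74.8 ± 7.30 and 63.9 ± 5.98 CPM. A count over the whole gene does not check its deleted part. Gli3, a member of the same family that acts mainly as a repressor, had 0 reads in each library. Against 77944561 reads in genes, a floor of 3 reads allows up to 0.0385 CPM. Its span is chromosome 13, 15463235 to 15730026.

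**Figure D2:**
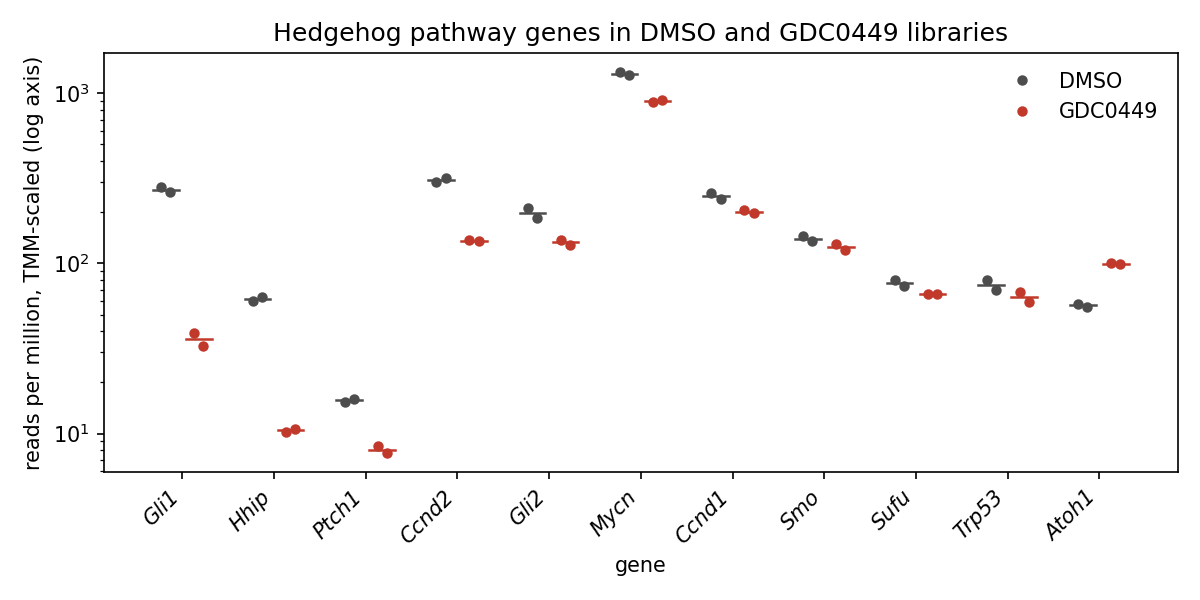
CPM on a log axis (vertical) of 11 panel genes (horizontal) in each library, with DMSO points in grey, GDC0449 points in red and a line at each group mean. Gli1 and Hhip lie lower in both GDC0449 libraries than in both DMSO libraries, by 7.61-fold and 5.90-fold.

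As a list, the Hedgehog targets were lower (camera adjusted p = 1.36e-24; adjusted p = 0.136 with an estimated correlation). Of 10 tested members 6 fell and 1 rose, over all genes and adjusted over the list alone. Bcl2, an inhibitor of apoptosis, was also among those that fell, and missed the fold threshold on log2(FPKM + 1) at -0.51. The riser was Atoh1 (ENSMUSG00000073043, chromosome 6, 64729125 to 64731245), the transcription factor that maintains granule neuron progenitors. It went from 56.7 ± 2.01 to 99.8 ± 0.957 CPM (adjusted p = 6.60e-14). Hedgehog signal transduction components were not called as a list (camera adjusted p = 0.763), and 1 of 31 members rose, over all genes and adjusted over the list alone. Their median was 0.06 and their mean 0.05, while the test pointed downward. The riser, Arrb1, missed the threshold without either DMSO replicate, at adjusted p = 0.0844 and 0.0824. None of 45 genes of the primary cilium, where Smoothened acts, was called with edgeR, DESeq2 or limma-voom, although 16 had an unadjusted p under the threshold. Its list test gave an adjusted p of 0.767. The median of -0.02 turned to 0.01 with upper-quartile scaling.

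Replication genes were lower as a list, by a median log2 fold change of -0.28 (camera adjusted p = 4.00e-07; adjusted p = 0.191 with an estimated correlation). Of 55 members 3 fell, over all genes and adjusted over the list alone, Cdc45 and Fen1 among them. Cdc45 lay near the fold threshold and missed it without DMSO replicate 1, at -0.54, and with upper-quartile scaling, at -0.57. Fen1 shares 84.2% of its exonic bases with another gene, and its call was lost without any 1 of the libraries. On all 4 libraries it was also lost with DESeq2, limma-voom and upper-quartile scaling, at adjusted p of 0.288, 0.0541 and 0.0596. Genes of G2 and mitosis were lower as a list by a median of -0.11 (camera adjusted p = 0.0214; adjusted p = 0.483 with an estimated correlation; 0.104 with the filter at 5 CPM). The list's median level was 93.5 CPM, and all tested genes at 50 to 200 CPM had a median log2 fold change of -0.06. Camera set the list against all tested genes, whatever their level. None of the 67 was called with edgeR, DESeq2 or limma-voom, and 33 had an unadjusted p under the threshold. Incenp and Mybl2 had log2 fold changes of -0.36 and -0.47. Cell cycle inhibitors were not called as a list (adjusted p = 0.673): of 20 members 1 rose and 1 fell, over all genes and adjusted over the list alone. Cdkn1a, which encodes p21, fell 2.39-fold, from 57.8 ± 2.30 to 24.2 ± 2.87 CPM. Gadd45b rose, a call that was lost without either DMSO replicate or GDC0449 replicate 1. On all 4 libraries it was also lost with DESeq2, limma-voom and no filter, at adjusted p of 0.315, 0.0600 and 0.196.

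The lists of 3 stages of the granule neuron lineage were higher, although many members were not called. Progenitor markers were higher (camera adjusted p = 2.95e-05; adjusted p = 0.227 with an estimated correlation), with 5 of 11 risen and 0 fallen, over all genes and adjusted over the list alone. Besides Atoh1 these were Meis1, Cxcr4, Mfap4 and Zic4, with Meis1 going from 67.4 ± 6.13 to 131 ± 5.21 CPM. Early postmitotic neuron genes were higher (camera adjusted p = 1.34e-15; adjusted p = 0.136 with an estimated correlation), with 11 of 33 risen and 0 fallen, over all genes and adjusted over the list alone. Dcx, a microtubule protein of migrating neurons, rose 2.29-fold, from 93.5 ± 6.50 to 214 ± 2.63 CPM. Elavl4 and Neurod1 rose 2.34-fold and 1.81-fold. Genes of mature granule neurons and synapses were higher (camera adjusted p = 4.90e-06; adjusted p = 0.227 with an estimated correlation), with 11 of 24 risen and 1 fallen, over all genes and adjusted over the list alone. Cbln1, a secreted synapse organiser, rose 2.47-fold, to 86.6 ± 2.08 CPM, and Reln and Syt1 rose 1.78-fold and 2.02-fold. Cplx2, a regulator of vesicle fusion, fell from 129 ± 0.905 to 52.6 ± 3.46 CPM.

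Markers of other cell types moved in different ways. Astrocyte markers were higher (camera adjusted p = 0.00148; adjusted p = 0.256 with an estimated correlation), with 4 of 10 risen over all genes and 5 adjusted over the list alone, and 0 fallen in either. The glutamate transporter gene Slc1a2 rose from 78.0 ± 7.69 to 177 ± 1.96 CPM and Sparcl1 from 15.8 ± 1.22 to 34.8 ± 0.840 CPM. Aldoc rose also, but not without DMSO replicate 2 (adjusted p = 0.0579). Neural stem and glial progenitor genes were not called as a list (adjusted p = 0.673); 3 of 12 rose and 2 fell, over all genes and adjusted over the list alone. Sox8 and Vim rose 2.46-fold and 1.61-fold, and Sox9 fell from 50.5 ± 0.517 to 29.8 ± 0.142 CPM. Oligodendrocyte lineage markers were not called (adjusted p = 0.763). Their median was -0.02, or 0.01 with upper-quartile scaling, with a mean of 0.11 and a test pointing upward. Of 7 members 1, Cnp, rose, over all genes and adjusted over the list alone, and lost its call without either DMSO replicate, at 0.222 and 0.147, or GDC0449 replicate 2, at 0.156.

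Microglia and macrophage markers were not called as a list (adjusted p = 0.673), and 2 of 7, Lyz2 and Tyrobp, fell, over all genes and adjusted over the list alone. Both were scarce, at 3.55 ± 0.853 and 0.934 ± 0.170 CPM in DMSO. Fibroblast and meningeal markers were not called (adjusted p = 0.767), and 3 of 6, all collagen genes, rose, over all genes and adjusted over the list alone. The highest of these, Col6a1, was at 1.92 ± 0.367 CPM in GDC0449. All 5 of these calls were lost without either DMSO replicate, at adjusted p of 0.0592 to 0.267. Without GDC0449 replicate 1 Tyrobp was lost (0.0579), and without GDC0449 replicate 2 Col3a1 and Col6a1 were lost (0.153 and 0.222). Lists with under 5 tested members had no set test. Of 4 endothelial and pericyte markers Pecam1 rose and Pdgfrb fell, both below 1.5 CPM on average in each group. Without DMSO replicates 1 and 2 in turn, Pecam1 was lost at adjusted p of 0.292 and 0.108 and Pdgfrb at 0.0742 and 0.194. Pecam1 was also lost without GDC0449 replicate 2 (0.209) and Pdgfrb without GDC0449 replicate 1 (0.134). Of 4 unipolar brush cell markers 2 rose, among them Otx2, from 59.6 ± 1.95 to 105 ± 3.76 CPM. Of 2 tested GABAergic neuron markers Lhx1 rose 1.92-fold, to 144 ± 2.57 CPM. Of 3 multiciliated and choroid plexus markers Otx2 and Aqp1 rose, Aqp1 not without either DMSO replicate (adjusted p = 0.0816 and 0.133). The counts in these 4 lists were equal when adjusted over the list alone.

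**Figure D3:**
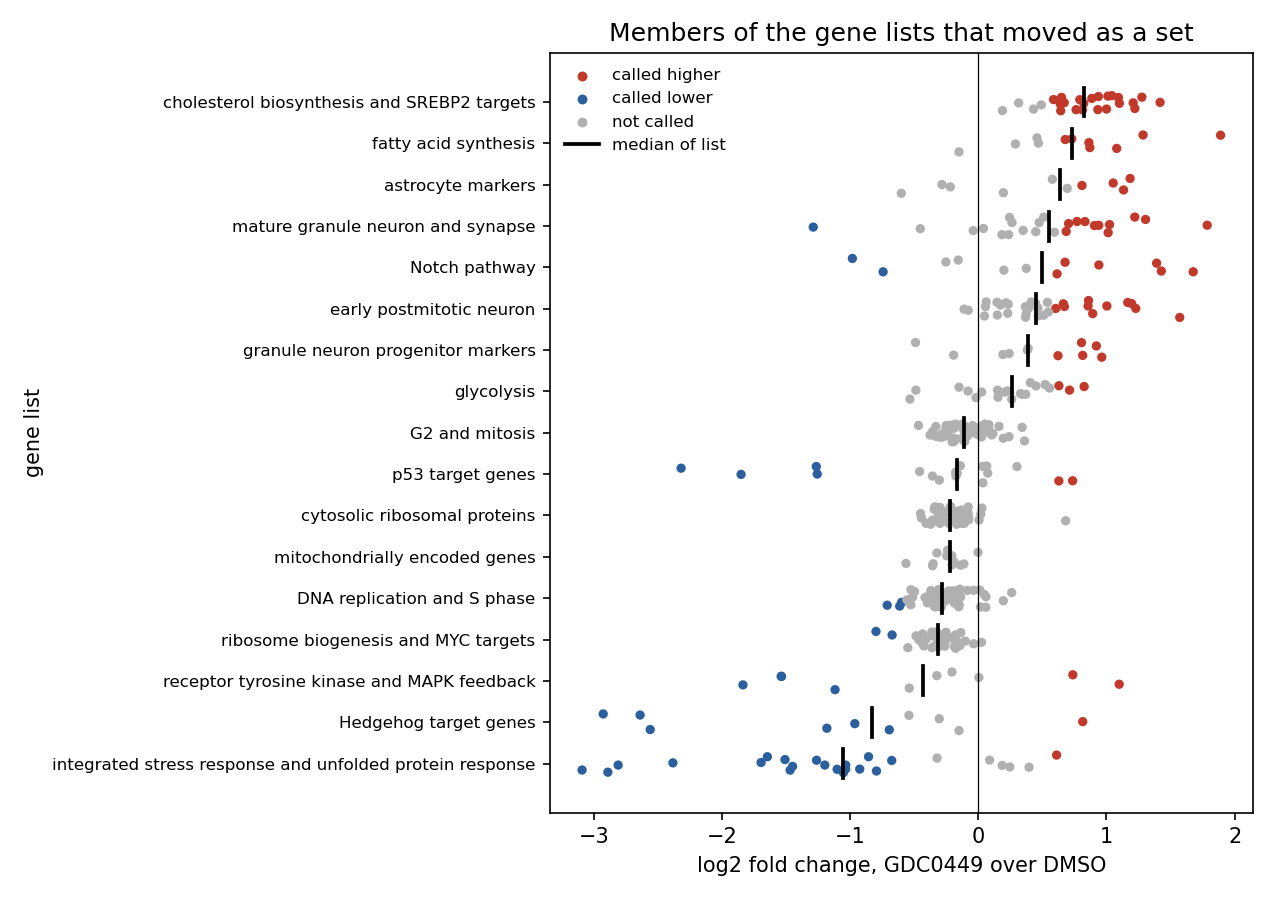
Log2 fold changes, GDC0449 over DMSO (horizontal axis), of the tested members of the 17 called gene lists (vertical axis, ordered by median), each point 1 gene, red if called higher, blue if called lower and grey if not called, with a black bar at the list median. The list of the integrated stress response and unfolded protein response has a median of -1.05. The Hedgehog target list has a median of -0.83, and the cholesterol list has a median of 0.82.

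Most listed genes of lipid synthesis rose. Of 25 genes of cholesterol synthesis and SREBP2 targets 21 rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 7.95e-36; adjusted p = 0.227 with an estimated correlation). All 25 had log2 fold changes above 0, with a median of 0.82. Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), an enzyme of the mevalonate pathway, rose 2.33-fold, from 130 ± 4.56 to 304 ± 0.229 CPM (adjusted p = 4.56e-23). Insig1 rose 2.42-fold. Of 11 genes of fatty acid synthesis 7 rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 1.27e-17; adjusted p = 0.308 with an estimated correlation). Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), a fatty acid desaturase, rose 3.71-fold, from 85.4 ± 8.89 to 317 ± 19.7 CPM. Its paralog Scd2 was more abundant and rose 2.44-fold, from 1093 ± 58.8 to 2665 ± 103 CPM. Glycolysis genes were higher (camera adjusted p = 0.00249; adjusted p = 0.802 with an estimated correlation; 0.139 with fry). Of 21 members 3 rose and 0 fell, over all genes and adjusted over the list alone. Aldoa rose 1.77-fold. Hk1 and Pfkl rose by less. Without DMSO replicate 2 Hk1 was under the fold threshold at 0.53 and Pfkl had an adjusted p of 0.0813, and without GDC0449 replicate 1 Pfkl was under the fold threshold at 0.56.

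Hypoxia response genes went both ways and were not called as a list (adjusted p = 0.783), with a median of 0.21 and a mean of 0.14 against a test pointing downward. Of 16 members 2 rose and 2 fell, over all genes and adjusted over the list alone. Vegfa, which encodes an angiogenic growth factor, fell from 162 ± 4.41 to 76.7 ± 3.65 CPM and the endoplasmic reticulum oxidase gene Ero1l from 165 ± 8.27 to 58.0 ± 7.82 CPM. Egln3 rose from 3.81 ± 0.139 to 7.86 ± 0.409 CPM. Ankrd37 also rose, a call lost without either DMSO replicate or GDC0449 replicate 2, at adjusted p of 0.426, 0.310 and 0.653. Nuclear-encoded oxidative phosphorylation genes were not called as a list (adjusted p = 0.186), but were lower without DMSO replicate 2 (0.00352) and without a filter on low counts (0.0302). None of 44 was called with edgeR in the main fit or with limma-voom, 1 was with DESeq2, and 18 had an unadjusted p under the threshold. The one called with DESeq2, Uqcrq, had a log2 fold change of -0.58 in the main fit. With edgeR it passed without a filter on low counts, at -0.586. Its log2 fold change was -0.67 without DMSO replicate 2 and -0.60 without GDC0449 replicate 1. Mitochondrially encoded genes were lower by a median of -0.22 (camera adjusted p = 0.0442; adjusted p = 0.802 with an estimated correlation). That call was lost without DMSO replicate 2 and without GDC0449 replicate 1. It was also lost with upper-quartile scaling, at 0.0519, the filter at 5 CPM, at 0.104, and directional fry, at 0.181. All tested genes over 200 CPM had a median of -0.08. None of the 12 was called with edgeR, DESeq2 or limma-voom, and 7 had an unadjusted p under the threshold. Mitochondrial reads made up 2.39% and 2.48% of reads in genes in DMSO and 2.12% and 2.26% in GDC0449.

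Genes of ribosome production were lower by small amounts. Ribosome biogenesis and MYC targets were lower by a median of -0.31 (camera adjusted p = 4.29e-10; adjusted p = 0.227 with an estimated correlation), with 37 of 38 negative and 2 called lower, over all genes and adjusted over the list alone. These were Srm, which encodes spermidine synthase and fell from 117 ± 8.10 to 67.5 ± 6.29 CPM, and the ribosome assembly gene Rrs1, from 103 ± 2.09 to 64.4 ± 0.848 CPM. Cytosolic ribosomal protein genes were lower by a median of -0.22 (camera adjusted p = 1.84e-06; adjusted p = 0.695 with an estimated correlation; 0.0957 with fry). All tested genes over 200 CPM had a median of -0.08. None of 51 was called with edgeR, DESeq2 or limma-voom, and 40 had an unadjusted p under the threshold. Replication-dependent histones, whose messages lack poly(A) tails, were scarce and not called as a list (adjusted p = 0.571). Of 7 tested members 2 rose, over all genes and adjusted over the list alone. Those, Hist1h2bc and Hist1h4i, were lost without DMSO replicate 2 (adjusted p = 0.179 and 0.212), Hist1h4i also without DMSO replicate 1 and GDC0449 replicate 2 (0.269 and 0.334).

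The integrated stress response and unfolded protein response list had the smallest p of the 35 lists (camera adjusted p = 2.41e-52; adjusted p = 0.136 with an estimated correlation). Of 25 members 19 fell and 1 rose, over all genes and adjusted over the list alone, with a median of -1.05. Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032), a pseudokinase induced by the transcription factors Atf4 and Ddit3, fell from 202 ± 10.9 to 23.7 ± 0.389 CPM (adjusted p = 8.42e-37). Chac1, a glutathione-degrading enzyme, fell from 66.2 ± 2.77 to 12.7 ± 1.02 CPM, and Ddit3 from 238 ± 11.2 to 76.1 ± 0.0345 CPM. Vldlr fell 3.24-fold. The riser was Sdf2l1, a gene of the endoplasmic reticulum, at a log2 fold change of 0.61.

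p53 target genes were lower as a list (camera adjusted p = 0.00281; adjusted p = 0.256 with an estimated correlation; 0.0539 on log2(FPKM + 1)), with 4 of 18 fallen and 2 risen, over all genes and adjusted over the list alone. The genotype in the labels is Trp53-/-. Besides Cdkn1a, Sesn2 fell from 161 ± 7.86 to 44.6 ± 2.68 CPM and the receptor gene Eda2r from 14.6 ± 3.63 to 2.89 ± 0.265 CPM, while Sesn1 rose 1.67-fold. Apoptosis regulators were not called (adjusted p = 0.783), with a median of -0.06 and a mean of 0.03, and a test pointing downward. Of 19 members 1 rose and 1 fell, over all genes and adjusted over the list alone. The riser was Bmf, a proapoptotic gene, from 3.28 ± 0.538 to 12.8 ± 0.480 CPM, and the other was Bcl2, from 33.0 ± 2.30 to 20.4 ± 0.152 CPM. None of 6 heat shock genes was called with edgeR, DESeq2 or limma-voom, with 3 at an unadjusted p under the threshold and a list adjusted p of 0.767. Their median of -0.03 turned to 0.01 with upper-quartile scaling. Immediate early genes were not called (adjusted p = 0.438), with a median of 0.06, a mean of -0.13 and a test pointing downward. Of 26 members 3 rose and 3 fell, over all genes and adjusted over the list alone. Atf3, which also belongs to the stress list, fell from 13.0 ± 0.442 to 1.85 ± 0.0686 CPM and Klf4 from 11.1 ± 0.625 to 4.52 ± 0.0296 CPM.

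Receptor tyrosine kinase and MAPK feedback genes were lower (camera adjusted p = 0.000385; adjusted p = 0.371 with an estimated correlation; 0.203 on log2(FPKM + 1)). Of 10 members 4 fell and 2 rose, over all genes and adjusted over the list alone. Etv5, a transcription factor induced by FGF signalling, fell from 117 ± 7.01 to 40.3 ± 0.0990 CPM and the ERK phosphatase gene Dusp6 from 84.7 ± 2.90 to 39.0 ± 0.736 CPM. Dusp4 rose 1.67-fold. Notch pathway genes were higher (camera adjusted p = 0.0325; adjusted p = 0.695 with an estimated correlation), with 6 of 12 risen and 2 fallen, over all genes and adjusted over the list alone. The list was not called without DMSO replicate 1, DMSO replicate 2 or GDC0449 replicate 1, at 0.0765, 0.235 and 0.0590, nor with the filter at 5 CPM, at 0.0569, or fry, at 0.0957. The effector gene Hey1 rose from 13.4 ± 1.44 to 36.3 ± 0.00206 CPM and the ligand gene Dll3 from 25.6 ± 2.30 to 49.3 ± 2.65 CPM, and Dtx4 fell 1.98-fold.

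The remaining signalling lists were not called. Of 16 interferon response genes 2 rose, Rsad2 and Stat2, over all genes and adjusted over the list alone (list adjusted p = 0.438), and Stat2 missed the fold threshold on log2(FPKM + 1) at 0.54. Of 9 Wnt targets Apcdd1 rose and Tnfrsf19 fell, over all genes and adjusted over the list alone (list adjusted p = 0.783). Both were lost without DMSO replicate 2 (0.0630 and 0.0615). Of 8 BMP and TGF-beta response genes Id2 rose and Id1 fell, over all genes and adjusted over the list alone (list adjusted p = 0.614), with a median of -0.15, a mean of 0.03 and a test pointing upward. Id2, an inhibitor of basic helix-loop-helix factors, rose from 20.7 ± 0.187 to 53.2 ± 0.624 CPM, and Id1 was lost without either DMSO replicate (0.0621 and 0.0997). None of 7 YAP and TAZ targets was called with edgeR, DESeq2 or limma-voom, with 3 at an unadjusted p under the threshold. Their list adjusted p was 0.673, with a median of 0.14, a mean of -0.03 and a test pointing upward. Of 7 genes of IGF signalling 2 rose and 2 fell, over all genes and adjusted over the list alone (list adjusted p = 0.673), with a median of 0.06, a mean of -0.14 and a test pointing downward. Igfbp5 rose 2.54-fold, and Igfbp4 and Irs2 fell 3.32-fold and 2.06-fold.

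Of the 12 highest and 12 lowest genes at a mean of at least 5 CPM, most belonged to none of these lists. Lama1 (ENSMUSG00000032796, chromosome 17, 67697259 to 67822647), which encodes a laminin chain of basement membranes, had the largest fall of them, 20.7-fold, from 59.0 ± 2.49 to 2.84 ± 0.600 CPM (adjusted p = 4.06e-34). Saa3, Steap1, Fibcd1, Synpo, Soat2, Gpr153 and Ppp1r15a fell between 6.40-fold and 14.5-fold. Ppp1r15a, a phosphatase subunit that reverses the integrated stress response, went from 143 ± 5.15 to 22.4 ± 0.522 CPM. Chodl (ENSMUSG00000022860, chromosome 16, 78930948 to 78951733), a membrane lectin gene, had the largest rise of them, 8.14-fold, from 2.81 ± 0.199 to 23.0 ± 0.723 CPM (adjusted p = 3.44e-23). Myod1 and Cdh15, which encode a myogenic transcription factor and M-cadherin, rose 7.53-fold and 6.23-fold, from 1.46 ± 0.0460 and 3.22 ± 0.339 CPM. Pnpla3, Papln, Nppc, Cyp11a1, Cthrc1, Kcna2, B3galt2 and Vipr1 rose between 3.76-fold and 6.18-fold. Of these, B3galt2 was lost without DMSO replicate 2 (adjusted p = 0.0579).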

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

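Among the tests given here, those of depth and of DNA reads were chosen only after the result was seen, and that of host genes was set down before its result.

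Reads in no gene were a larger share in GDC0449 than in DMSO, by 1.54 percentage points between the group means, in data outside the gene comparison. On the deposited FPKM values, 22 genes that the count test did not cover were higher in GDC0449, and 17 were lower. The Purkinje cell gene Pcp4 (chromosome 16, 96467606 to 96525793) stood out among these: its FPKM was 0.423 ± 0.111 in DMSO and 3.60 ± 0.746 in GDC0449 (SD, n = 2), while its counts were 0, 0, 0 and 1. Other genes share 23.7% of its exonic bases.

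Higher calls made up 75.2% of calls below 5 CPM and 64.1% of calls at 5 CPM or more; without the fold threshold 699 genes were higher and 234 lower below 5 CPM, and 2095 and 2559 at 5 CPM or more. Deeper sequencing of the GDC0449 libraries is argued against: with every library thinned to the smallest total, 76.4% of the 776 calls below 5 CPM were higher. Reads from DNA are argued against as the whole cause: 1974 olfactory and vomeronasal receptor genes went from 668 reads in DMSO to 1156 in GDC0449, which goes with more such reads, but their gain per kb was 0.392% of that of the 674 weakly expressed higher genes. Unspliced RNA of abundant host genes is argued against as the whole cause: 2885 genes below 5 CPM that overlap no gene of 5 CPM or more had a median log2 fold change of 0.253 (bootstrap interval 0.22 to 0.28), and 1782 overlapping ones had 0.14. The treatment and a difference in library preparation between the groups both stay open, untested.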

How the results depend on the processing

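The settings on log2(FPKM + 1) and the legacy fit were chosen only after the results were seen. Of the 1343 higher and 596 lower genes, 0 were called in the opposite direction under the settings run. The count of higher genes was 746 without a filter, 799 with the filter at 5 CPM, 777 with DESeq2, 520 on log2(FPKM + 1) and 2794 without a fold threshold. The count of lower genes was 366 with the filter at 5 CPM, 350 on log2(FPKM + 1) and 2793 without a fold threshold. All 777 higher genes of DESeq2, and 429 of its 447 lower ones, were among the main calls. Leaving out single libraries gave 500 to 1221 higher and 351 to 605 lower genes; fewer samples are part of that setting's construction, and the lowest counts came without DMSO replicate 2. Scaling moved the share of higher calls from 69.3% to 68.5% with relative log expression and to 73.2% with upper-quartile factors, and the median log2 fold change of all genes by -0.01 and 0.03. Thinning every library to the smallest total gave 1273 higher and 548 lower genes. The legacy fit gave 1333 and 588.

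Of the 17 called lists, 0 passed with an estimated correlation, although 7 of the 35 lists had an unadjusted p under the threshold there. The smallest adjusted p was 0.136, for the Hedgehog targets among others. Estimates were below the preset 0.01 for Hedgehog targets (-0.0733), early postmitotic neuron (-0.0288) and progenitor markers (-0.0487). In these lists a correlation above the preset cannot account for the loss. Cholesterol and fatty acid synthesis were estimated above it, at 0.431 and 0.864. Directional fry called 15 lists, 13 of them in the main result, and fry in either direction called 32. Lists whose direction turned were not called in the main result or under that setting. Hedgehog signal transduction components ranged from 0.618 to 0.858 over the omitted libraries, hypoxia from 0.473 to 0.865, and BMP and TGF-beta response from 0.543 to 0.824. Hypoxia also turned without a filter (0.761) and on log2(FPKM + 1) (0.288), and Wnt and IGF turned on log2(FPKM + 1) (0.940 for each). The cause of these changes was not tested. Across named genes and settings, 1801 results were alike in direction and call, 124 lost the call, 8 gained it and 0 turned. A further 47 results of named genes had no value under a setting. Without a filter, where more genes were tested, 20 named genes lost their call. With counts thinned to the smallest library, Egfr and Fen1 did. With DESeq2, 10 named genes lost it, Arrb1, Cnp, Col6a1, Fen1, Gadd45b, Hist1h2bc, Id1 and Pdgfrb among them.

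The replicate numbers were not taken to pair the samples, since the labels do not say what a number marks and there are only 2 pairs. The deviations of libraries with one number correlated at 0.035 across the 15472 tested genes and at 0.47 across the 4823 genes above 50 CPM. With the replicate block, 1407 genes were higher and 615 lower, of which 1336 and 592 were main calls, and 17 lists were called, the same 17. Hypoxia, not called, turned in direction (0.750).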

Other observations

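The gene families below, the gene-order test, the test of neighbours and the Gli3 test were chosen only after the result was seen; the test on genes that are not protein coding was set down before its result.

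Beyond the stress list, some genes of cytosolic aminoacyl-tRNA synthetases and amino acid transporters fell. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, 10 fell and 0 rose in edgeR, with a median log2 fold change of -0.60 (camera adjusted p = 1.85e-21; adjusted p = 0.103 with an estimated correlation). Nars fell 2.32-fold, from 738 ± 19.3 to 318 ± 8.70 CPM (SD, n = 2), and Gars fell 2.10-fold, from 616 ± 2.04 to 293 ± 8.22 CPM. The mitochondrial synthetases had a median of -0.10 (adjusted p = 0.224), and the difference between these families was not tested. Of 20 amino acid transporters 9 fell and 2 rose (camera adjusted p = 6.43e-17; adjusted p = 0.102 with an estimated correlation). Slc7a5, Slc3a2 and Slc7a11 of this family also belong to the stress list; outside it, Slc7a3 fell 3.30-fold and Slc7a1 fell 2.43-fold.

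Some members of families of axon guidance and adhesion rose. Of 19 ephrins and Eph receptors 10 rose and 1 fell (camera adjusted p = 1.71e-07; adjusted p = 0.108 with an estimated correlation); Epha4 rose 2.43-fold, from 20.7 ± 0.578 to 50.4 ± 2.13 CPM, and Epha8 fell 3.65-fold. Of 24 semaphorins and plexins 8 rose and 0 fell in edgeR (camera adjusted p = 2.28e-07; adjusted p = 0.144 with an estimated correlation), with Sema7a going from 117 ± 0.274 to 306 ± 14.4 CPM. Of 48 protocadherins 12 rose (camera adjusted p = 6.79e-05; adjusted p = 0.108 with an estimated correlation). Reads of this family were not all counted: Pcdhga10 had no counts in any library at a mean FPKM of 12.7. Of 40 potassium channel subunits 14 rose and 6 fell (camera adjusted p = 0.00445; adjusted p = 0.112 with an estimated correlation), with Kcna2 rising 3.87-fold. Of 9 genes of skeletal muscle determination and the muscle acetylcholine receptor 5 rose (camera adjusted p = 7.68e-05; adjusted p = 0.108 with an estimated correlation): Myod1, Cdh15, Tnnt1, Chrnb1 and Myog. Of 37 proteasome subunits 0 passed both the adjusted p and the fold threshold in edgeR, with a median log2 fold change of -0.16, while camera called the family lower (adjusted p = 0.0240; adjusted p = 0.144 with an estimated correlation). The medians of the 9 families kept their sign with relative log expression and upper-quartile scaling. The families were not tested without single libraries, and their p-values are not independent evidence, since the results had been seen.

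By the mean over the 4 libraries, 3 runs of neighbouring tested coding genes held a window of 9 genes with high median read density. The chromosome 1 run went from 149829618 to 152902646 (19 genes, with Ivns1abp at 6945 CPM and Tpr at 5378 CPM). That on chromosome 10 went from 127095650 to 127341974 (13 genes, Gli1 and Ddit3 among them). That on chromosome 12 went from 10390772 to 16610966 (12 genes, Mycn and Ddx1 among them). Coding genes that failed the expression filter were left out of the order, and single libraries were not scanned. Of the 12 genes on chromosome 12 only 6 lay above the genome-wide upper quartile of 16.3 CPM per kb. Median densities of the chromosome 10 run were 81.0 and 76.8 in DMSO and 47.5 and 44.5 in GDC0449. The run did not fall as a whole, since its genes had a median log2 fold change of -0.0483. Its only called genes were Ddit3 and Gli1, at -1.65 and -2.93, whose falls changed which gene lay at the middle rank. Chance order of genes is argued against: of 1000 permutations of gene order other than those that set the density threshold, 0 had 3 such runs and the most in any was 2, a share given as 0.1%, the smallest they can resolve. Whether Hedgehog-dependent activity raised the regions of Gli1 and Mycn cannot be told apart from other causes: their 23 neighbours had a median log2 fold change of -0.0470 (bootstrap interval -0.21 to 0.45) but went both ways, with 2 called higher and 1 lower. DNA copy gain is a candidate explanation: the 104 genes there that are not protein coding had a median density of 0.0365 CPM per kb, against 0 elsewhere, which 0 of 10000 random draws reached, a share given as 0.01%, the smallest they can resolve. Shared activity of each region would give the same, and no DNA was measured.

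Gli3 had 0 reads in each library, and the other gene inside its span had none. Loss of the locus and silence of an intact gene cannot be told apart here: of 823 protein-coding genes with at least 5000 exonic bases and a long span, 100, or 12.2%, had 0 reads in all libraries, so silence is common. Its neighbours Hecw1 and Inhba also had 0 reads, while Mrpl32 and Psma2 had 1452 and 5455.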
